A study of Mus musculus with 15 samples.

How the data were processed

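Polyadenylated RNA from single whole embryos was made into stranded libraries (TruSeq Stranded mRNA), per the labels' protocols. The labels give the strain background as a mix of C57Bl6 and CD-1. The submitters' processing notes name STAR, Picard, featureCounts, DESeq2, kallisto and the build mm10, without roles or versions. The authors deposited a table of signal values, gene counts divided by a size factor per library, which are called normalized counts here. Dividing the values by the step of each library gave whole reads for 100.0% of values (within 0.01), so that reads per library could be recovered; the deposited size factors then ran from 0.8495 to 1.0735. Between 76.9% and 79.1% of the recovered counts from 1 to 20 were even, as if both mates of a read pair had been counted, so independent fragments may be fewer than the reads given. The table held 45232 genes, of which 18400 were at 0 in every library; 98.6% of the identifiers had a symbol in the GENCODE annotation of GRCm38 (mm10), which also gave coordinates. In 1 cell a stray letter before the number was left out. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 11.5 to 41.2). Separate embryos differ beyond that noise in any case, and counting both mates would raise these values. Each library came from a single embryo and counted as 1 replicate. Depth, 48.8 to 61.3 M reads, limits low genes, and the 3 wild-type embryos limit the precision of every comparison with wild-type.

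The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1) over 16430 genes with a mean normalized count of at least 10 in all libraries. A fold change is therefore on the log2(value + pseudocount) scale, which understates the change of low genes. A single fit with 3 groups covered all 15 libraries, and Benjamini-Hochberg adjusted p under 0.05 counted as called. Apela KO versus wild-type was the mean of both strain effects. On simulated data with the same group sizes, the fit of Apela KO versus wild-type called 58.6% of 99 genes changed by 0.5 on the log2 scale and 84.5% of 97 genes changed by 1, with 11 unchanged genes called among 16312 tested. The simulated libraries were independent, without shared litters or batches, so these rates hold only for independent embryos. Gene lists were fixed before the data were examined, 29 in all: embryonic, extraembryonic and maternal tissues, Hox genes as a measure of stage, signalling targets, stress, metabolism, mitochondrially encoded genes, neighbours of Apela, and sex genes. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. No list was called in any of the 4 comparisons with an estimated correlation; fry, a rotation test of whether a list's genes move on balance one way, called 3, 2, 4 and 5 lists in Apela KO versus wild-type, NEO-IN versus wild-type, NEO-OUT versus wild-type and NEO-IN versus NEO-OUT. A list score is the mean over members of the log2 value centred on all libraries.

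Named genes followed a rule also fixed before the data were examined: Apela, Apln and Aplnr; the 10 largest increases and 10 largest decreases in Apela KO versus wild-type and 5 of each in the other comparisons, among called genes with a mean normalized count of at least 50 and a symbol that is not a gene model name; and from each list up to 4 called members, or the 2 with the smallest p. Sex genes served only as a check of embryo sex. The result of 1 named gene is not reported here; other named genes are not each given in each comparison, and uncalled members mostly enter through their list. Alternatives changed the pseudocount, the filter, the scaling, the variance model, the samples fitted, covariates, the libraries and the unit of the test (runs of 3 consecutive libraries as a block or as means), and applied edgeR 4.0.16 and DESeq2 1.42.0 to the recovered reads. edgeR's quasi-likelihood test called 488 genes in Apela KO versus wild-type, 525 in NEO-IN versus wild-type, 1059 in NEO-OUT versus wild-type and 2157 in NEO-IN versus NEO-OUT. Several protein-coding mitochondrial genes, such as mt-Co2 and mt-Atp6, were near 0 in every library and did not enter the test. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.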

Results

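RNA was measured in 15 individual whole mouse embryos at embryonic day 7.5, when gastrulation is laying down the mesoderm, with embryonic and extraembryonic tissues kept together. Apela encodes a small secreted peptide that, like apelin (Apln), is a ligand of the apelin receptor Aplnr. There were 3 wild-type embryos and 12 Apela knockout embryos (Apela KO), of which 6 came from the strain NEO-IN and 6 from the strain NEO-OUT. The knockout embryos came from matings of homozygous knockout parents, and all embryos were matched in stage by morphology. Library depth ran from 48.8 to 61.3 M recovered reads, and 20427 to 21059 genes were detected per library. The labels gave neither sex, litter nor batch. All 3 wild-type libraries held Xist RNA and next to no Y-linked reads, whereas 3 NEO-IN libraries (1, 2 and 3) and 2 NEO-OUT libraries (9 and 12) held 7843 to 8995 reads of 4 Y-linked genes. Within each strain, splitting by consecutive numbers (1 to 3 and 4 to 6, 7 to 9 and 10 to 12) parted the libraries farther than any other split into 3 and 3. Single pairs did not always follow these runs, as NEO-OUT 9 lay closer to 10 than to 7 or 8. The labels do not say whether these runs share a litter or a batch.

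Apela RNA was reduced in every knockout embryo. Apela (ENSMUSG00000079042.6, a protein-coding gene on chromosome 8 from 65028417 to 65037336 in GRCm38) had a normalized count of 1660 ± 505 (SD, n = 3) in wild-type, 11.5 ± 7.24 (SD, n = 6) in NEO-IN and 69.6 ± 21.6 (SD, n = 6) in NEO-OUT. The log2 fold change was -7.16 (SE 0.35, limma adjusted p = 1.22e-09) in NEO-IN and -4.56 (SE 0.35, limma adjusted p = 6.14e-07) in NEO-OUT. The residual signal was 6.05-fold lower in NEO-IN than in NEO-OUT (log2 fold change -2.60, SE 0.28, limma adjusted p = 2.03e-05), and all 6 NEO-IN libraries lay below all 6 NEO-OUT libraries. Apln and Aplnr were abundant and were not called in any comparison. In Apela KO versus wild-type their log2 fold changes were -0.11 (SE 0.07, limma adjusted p = 0.459) and -0.13 (SE 0.05, limma adjusted p = 0.191).

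**Figure D1:**
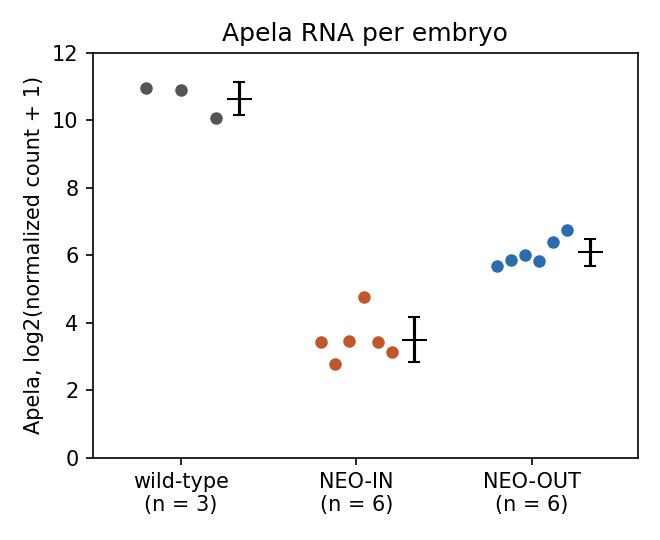
Apela RNA as log2(normalized count + 1) in each embryo, by group; each point is 1 embryo and the bars give the mean and SD. All 12 knockout embryos lie below the 3 wild-type embryos, and the NEO-IN embryos (mean normalized count 11.5) lie below the NEO-OUT embryos (69.6).

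Apela KO versus wild-type took the mean of both strain effects, with the strains weighted equally. Transcripts of the mitochondrial genome were lower in all 12 knockout embryos than in any wild-type embryo for mt-Nd1, mt-Co1, mt-Nd5 and mt-Cytb, which encode subunits of the respiratory chain. mt-Nd1 fell from 129000 ± 27700 (SD, n = 3) to 60000 ± 12200 (SD, n = 12), a log2 fold change of -1.11 (SE 0.17, limma adjusted p = 0.00129), and mt-Co1 had a log2 fold change of -0.98 (SE 0.14, limma adjusted p = 0.00117). Of the 7 mitochondrially encoded genes tested, 6 fell and none rose, both over all genes tested and adjusted over the list alone; mt-Nd6 had a log2 fold change of -0.52 and was not called. The list had a camera adjusted p of 4.15e-11 at the preset correlation, and an adjusted p = 0.138 with an estimated correlation. Mitochondrial RNA made up 0.789% to 1.12% of the normalized counts in the wild-type libraries and 0.302% to 0.602% in the knockout libraries.

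Targets of the stress-activated transcription factor p53 were higher as a list in the mean of both strains, but not in NEO-IN alone, where the median log2 fold change was 0.01 with 6 of 12 members positive (camera adjusted p = 0.508) and 1 called higher over all genes and over the list alone, Zmat3, which lost its call in 10 of 15 fits without 1 library. The median was 0.21 in NEO-OUT. In the mean of both strains all 12 members had positive fold changes and 3 were called higher, or 5 adjusted over the list alone (camera adjusted p = 6.31e-05; adjusted p = 0.182 with an estimated correlation). The called members were Eda2r, a receptor of the tumour necrosis factor family (log2 fold change 0.84, SE 0.15, limma adjusted p = 0.0067), the RNA-binding protein gene Zmat3 (0.25, SE 0.05, limma adjusted p = 0.0184) and Phlda3 (0.46, SE 0.10, limma adjusted p = 0.0233). In NEO-IN too, Zmat3 (2463 to 2878) and Phlda3 (839.3 to 1028) lay above every wild-type embryo (at most 2285 and 799.9). Phlda3 was not called there. Eda2r overlapped, at 128.8 in NEO-IN 5 against up to 138.6 in wild-type. Without wild-type embryo 1, 2 or 3 the adjusted p of Phlda3 was 0.0802, 0.0786 and 0.149, and that of Zmat3 was 0.1, 0.103 and 0.0581; Eda2r lost its call only without wild-type embryo 1 (0.0616). Extraembryonic ectoderm and trophoblast genes were also higher as a list, with positive fold changes in 12 of 13 members, 1 of them called over all genes and over the list alone (camera adjusted p = 0.00311; adjusted p = 0.5 with an estimated correlation, and 0.0716 among protein-coding autosomal genes). The called member was Rhox9, an X-linked homeobox gene, at 140 ± 19 (SD, n = 3) in wild-type and 298 ± 115 (SD, n = 12) in the knockouts (limma adjusted p = 0.0357), which lost its call without wild-type embryo 1, 2 or 3 (0.162, 0.0978 and 0.153). The list score lay between -0.41 and -0.27 in the wild-type embryos and between -0.35 and 0.62 in the knockouts.

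The lists of mesoderm and its derivatives were not called in this comparison. The median log2 fold change was -0.19 over 14 primitive streak genes (camera adjusted p = 0.0715), -0.19 over 14 cardiac mesoderm genes (0.12), -0.31 over 11 paraxial mesoderm and somite genes (0.0715), 0.18 over 16 primitive blood genes (0.279) and 0.01 over 11 endothelial genes (0.82), and no member of these 5 lists was called over all genes. Adjusted over the list alone, 1 paraxial gene was lower. The apelin pathway list was called lower (camera adjusted p = 0.000295; adjusted p = 0.138 with an estimated correlation) with 1 of 3 members called over all genes, Apela, and 2 adjusted over the list alone. The call of the apelin pathway list cannot be separated from the knockout of Apela itself. In total 25 of the 29 lists were not called, with adjusted p from 0.0715 to 0.942. Among other list members, Otx2, a transcription factor of the anterior epiblast and neural plate, was lower (log2 fold change -0.30, SE 0.06, limma adjusted p = 0.0197), as was Hmgcs1, an enzyme of cholesterol synthesis (-0.46, SE 0.09, limma adjusted p = 0.0073). Both lost their call without wild-type embryo 1 (0.106 and 0.0745) or 2 (0.133 and 0.0879).

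The long noncoding RNA Lncenc1 rose 41.8-fold, from 31 ± 5.53 (SD, n = 3) to 1350 ± 281 (SD, n = 12; log2 fold change 5.39, SE 0.16, limma adjusted p = 6.66e-13). Fgl1, a fibrinogen-like secreted protein gene on chromosome 8, went from 1.28 ± 1.11 (SD, n = 3), near the floor, to 63.3 ± 20.2 (SD, n = 12). The glycosyltransferase gene B3gnt3, also on chromosome 8, rose 4.64-fold (limma adjusted p = 0.000228), Rsad1 rose 2.45-fold (2.06e-05) and Gnpda1, an enzyme of amino sugar metabolism, rose 2.56-fold (0.00145). All 12 knockout embryos lay outside the wild-type range for each gene of this paragraph so far except Gnpda1, with 11 of 12. Among the decreases, Baiap2l1, an adaptor of the actin cytoskeleton, was 2.98-fold lower (limma adjusted p = 3.81e-07), the kinase family member Ulk4 was 2.99-fold lower (2.15e-05) and the helicase gene Mov10l1 was 2.71-fold lower (0.00264). These genes kept their calls whichever of the 15 libraries was left out. Gnpda1 lost its call with the trophoblast score as a covariate (adjusted p = 0.0675) and Mov10l1 with means of 3 consecutive libraries as the unit (0.139). For Lbp, Rps26-ps1 and AI662270, 7, 8 and 9 of 12 knockout embryos lay outside the wild-type range. The fixed rule also named Gstm6, Fkbp6, Fcgrt, AI662270 and Acp1 among the increases and the pseudogenes Rps26-ps1 and Tdpx-ps1, Triml2, Lbp and Ocel1 among the decreases, and each of these lost its call without at least 1 wild-type embryo. Without wild-type embryo 1, 2 or 3 the adjusted p was 0.157, 0.119 and 0.0675 for Gstm6 and 0.0541, 0.0517 and 0.0547 for Acp1. It was 0.0671 and 0.0508 for Fcgrt and 0.0524 and 0.0618 for Triml2 without embryo 1 or 2, 0.0872 and 0.0802 for Rps26-ps1 without embryo 1 or 3, and 0.0596 for Ocel1 without embryo 1. Fkbp6, AI662270, Tdpx-ps1 and Lbp lost their calls in 13, 10, 13 and 8 of the 15 fits that each left out 1 library.

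Across the genome, 465 of 16430 genes tested were called in Apela KO versus wild-type, 264 higher and 201 lower, and 89 of them changed by 2-fold or more (limma, Benjamini-Hochberg adjusted p under 0.05). Genes within 30 Mb of Apela on chromosome 8 were called more often than genes on other chromosomes, 55 of 380 (14.5%) against 391 of 15525 (2.52%; two-sided Fisher's exact p = 4.66e-24), with 32 higher and 23 lower. The share did not fall evenly with distance, at 20% within 10 Mb, 5.74% from 10 to 20 Mb, 16.7% from 20 to 30 Mb and 5.65% from 30 to 50 Mb. The total was 153, 160 and 200 without wild-type embryo 1, 2 and 3, 83 with the trophoblast list score as a covariate, 300 with the Y-linked level as a covariate, 175 with the 12 knockouts as 1 group and 188 with runs of 3 libraries as a random block. It was 73 with means of 3 consecutive libraries as the unit, 865 with array quality weights and 900 with DESeq2.

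**Figure D2:**
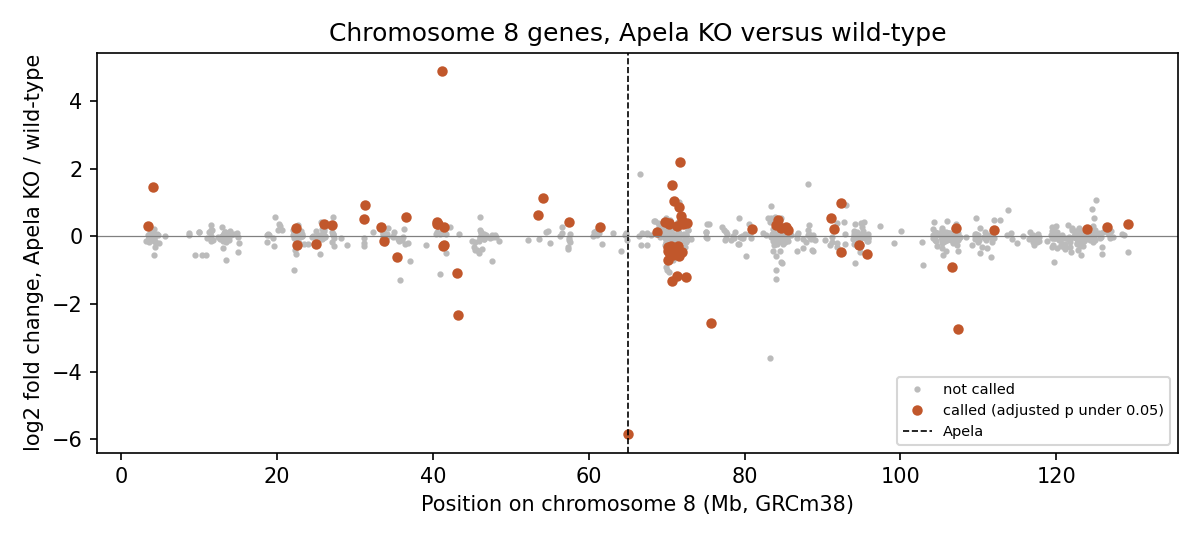
Log2 fold change of each tested gene on chromosome 8 in Apela KO versus wild-type (y axis) by its position in Mb in GRCm38 (x axis); coloured points are called genes and the dashed line marks Apela. Of the genes within 30 Mb of Apela 14.5% were called, and of those farther than 50 Mb 2.29%.

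NEO-IN versus wild-type asked which changes the first strain showed alone. Mitochondrially encoded transcripts were lower here too, with 6 of 7 called lower, or 7 adjusted over the list alone (camera adjusted p = 2.34e-12; adjusted p = 0.101 with an estimated correlation). mt-Nd1 was 2.38-fold lower (limma adjusted p = 0.000914). Ifi204, an interferon-inducible gene, was at 0 in all 3 wild-type embryos, at 770 ± 458 (SD, n = 6) in NEO-IN and at 0 in NEO-IN embryo 4, so that the mean was at least 260-fold higher against a floor of 3 reads per library. The pseudogene Znf41-ps rose 6.86-fold (limma adjusted p = 0.00214) and Lncenc1 rose 37.8-fold (4.98e-12). Abhd12b fell from 126 ± 61.9 (SD, n = 3) to 10.1 ± 15.1 (SD, n = 6; limma adjusted p = 0.004), and Triml2 on chromosome 8 was 7.31-fold lower (0.00341). The fixed rule also named Fgl1, Gstm6, Rps26-ps1 and Zfp990, of which the last 3 lost their calls in 12, 2 and 3 of the 15 fits without 1 library. The lists called besides these were hypoxia targets, lower with negative fold changes in all 9 members (camera adjusted p = 0.012; adjusted p = 0.572 with an estimated correlation), the apelin pathway (0.000112; adjusted p = 0.101 with an estimated correlation), and primitive streak lower, epiblast lower and trophoblast higher, each with an adjusted p of 0.0471 (adjusted p = 0.837 with an estimated correlation). None of the hypoxia, primitive streak or epiblast members was called over all genes, and over the list alone 2 hypoxia targets were. Hypoxia targets lost the call without wild-type embryo 1 (0.0871), and the other 3 lists without wild-type embryo 1 (0.0865, 0.0871 and 0.0988) or 2 (0.138, 0.185 and 0.138); without NEO-IN embryo 1, 2 or 6 the adjusted p was 0.0859, 0.057 and 0.229 for primitive streak and 0.0859, 0.0846 and 0.189 for epiblast, and without NEO-IN embryo 2 or 3 it was 0.151 and 0.0877 for trophoblast. The trophoblast list had 1 member called over all genes and 1 adjusted over the list alone. With the trophoblast score as a covariate, primitive streak lost its call and its median was no longer negative. In the apelin pathway list only Apela was called over all genes, so its call cannot be separated from the knockout of Apela itself.

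In total 489 genes were called in NEO-IN versus wild-type, 252 higher and 237 lower. The count was 239, 206 and 223 without wild-type embryo 1, 2 and 3, 108 with the trophoblast score as a covariate and 237 with runs of 3 libraries as a random block. It was 71 with their means as the unit, 800 with array quality weights and 928 with DESeq2.

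NEO-OUT versus wild-type asked the same of the second strain. p53 targets rose in NEO-OUT, with all 12 members positive and 6 called higher, or 9 adjusted over the list alone (camera adjusted p = 2.76e-08; adjusted p = 0.103 with an estimated correlation). Eda2r rose 2.50-fold (log2 fold change 1.32, SE 0.17, limma adjusted p = 0.000223), the cyclin gene Ccng1 1.51-fold (0.00146), Phlda3 1.58-fold (0.00267) and Perp, a membrane protein gene induced in cell death, 1.28-fold (0.00347). The heat shock genes Hspa1a and Hspa1b rose 4.02-fold and 3.52-fold (limma adjusted p = 0.0301 and 0.0206) and the immediate early gene Fos 1.48-fold (0.031), all higher in 6 of 6 embryos, but each lost its call without wild-type embryo 1, 2 or 3 (0.0785, 0.067 and 0.156 for Hspa1a, 0.0525, 0.0792 and 0.0973 for Hspa1b, 0.13, 0.0858 and 0.0816 for Fos). Hspa1a also lost it without NEO-OUT 9 or 10 (0.0505 and 0.0535), and Fos without NEO-OUT 10, 11 or 12 (0.0606, 0.0578 and 0.0516). The immediate early and heat shock list that holds these 3 genes was not called (camera adjusted p = 0.0636), with 7 of 10 members positive. Fos was also higher in all 6 NEO-IN embryos than in any wild-type embryo (116.4 to 166.5 against at most 111.8), though not called there. Mitochondrially encoded transcripts were lower, with 6 of 7 called over all genes and adjusted over the list alone (camera adjusted p = 8.93e-07; adjusted p = 0.354 with an estimated correlation).

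The Hox list and the paraxial mesoderm list were called lower in NEO-OUT, while primitive streak (camera adjusted p = 0.216) and node and notochord (0.153) were not called. The Hox list, whose genes come on in sequence as the axis forms, had negative fold changes in all 12 members and 2 called lower, Hoxb1 (log2 fold change -0.54, SE 0.15, limma adjusted p = 0.0355) and Hoxb2 (-0.44, SE 0.12, limma adjusted p = 0.0354), as when adjusted over the list alone, with a camera adjusted p of 0.0222 (adjusted p = 0.629 with an estimated correlation). Of 11 paraxial mesoderm genes, 2 were called lower, Foxc1 (-0.59, SE 0.13, limma adjusted p = 0.0118) and Tcf15 (-0.78, SE 0.18, limma adjusted p = 0.0161), also when adjusted over the list alone. The paraxial list had an adjusted p of 0.0366 (adjusted p = 0.463 with an estimated correlation). Otx2 was 1.33-fold lower (limma adjusted p = 0.00243) and lower in 6 of 6 embryos. The Hox list lost its call without wild-type embryo 1 (0.0574) or 3 (0.119), and the paraxial list without wild-type embryo 1 (0.0956). Without wild-type embryo 1, 2 or 3 the adjusted p was 0.131, 0.104 and 0.0967 for Hoxb1 and 0.129, 0.0768 and 0.133 for Hoxb2, which also lost its call without NEO-OUT 9 or 12 (0.0604 and 0.0508). It was 0.0827 for Foxc1 without embryo 1, and 0.0829 and 0.06 for Tcf15 without embryo 1 or 2. Of the 6 NEO-OUT embryos, 10 to 12 had the lowest scores. Their Hox scores were -0.94, -0.13 and -0.28, against 0.17, 0.01 and 0.01 in NEO-OUT 7 to 9 and -0.11 to 0.32 in wild-type. Their paraxial scores were -0.79, -0.27 and -0.15, against 0.24, 0.01 and -0.01 in NEO-OUT 7 to 9 and 0.05 to 0.40 in wild-type. The called genes Hoxb1, Hoxb2, Foxc1 and Tcf15 were lower in all 6 NEO-OUT embryos than in any wild-type embryo. Hoxb1 and Hoxb2 were not particular to NEO-OUT, as all 6 NEO-IN embryos also lay below every wild-type embryo. Hoxb1 was at 3385 to 3919 in NEO-IN against at least 4119 in wild-type, and Hoxb2 at 1021 to 1170 against at least 1263. Neither was called in NEO-IN versus wild-type.

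Visceral endoderm genes were higher in NEO-OUT, with 11 of 13 members positive and 3 called, or 4 adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.613 with an estimated correlation). The thyroid hormone carrier Ttr rose 1.37-fold (limma adjusted p = 0.0136; 0.0741 and 0.0766 without wild-type embryo 1 or 2), and the list lost its call without NEO-OUT embryo 11 (0.0725) or 12 (0.0608). The other called members, Apoa1 and Soat2, lost their calls in 12 and 9 of 15 fits without 1 library. Visceral endoderm scores were 0.16, 0.30 and 0.29 in NEO-OUT 10 to 12 but 0.05, -0.01 and -0.08 in NEO-OUT 7 to 9, near those of wild-type (-0.02 to 0). The trophoblast list was higher (camera adjusted p = 0.00694; adjusted p = 0.463 with an estimated correlation), with 1 of 13 members called, Esrrb, or 3 adjusted over the list alone. Esrrb lost its call in 11 of 15 fits. The apelin pathway list was lower (0.0112; adjusted p = 0.354 with an estimated correlation). Of that list only Apela was called, so its call cannot be separated from the knockout of Apela itself. Lncenc1 rose 46.2-fold and B3gnt3 4.94-fold, whereas the pseudogene Eif5al3-ps was 22.3-fold lower (limma adjusted p = 0.00583). Eif5al3-ps was also low in NEO-IN 2 and 3 (33.03 and 38.66, against 498.9 to 911 in wild-type). The fixed rule also named Fgl1, which kept its call whichever library was left out, and Glns-ps1, Gstm6, Rps2-ps13, Nr1h5 and Zfp979, which lost theirs in 12, 2, 2, 8 and 2 of the 15 fits. In total 1043 genes were called in NEO-OUT versus wild-type, 549 higher and 494 lower. The count was 383, 421 and 500 without wild-type embryo 1, 2 and 3, 336 with the trophoblast score as a covariate, 583 without NEO-OUT 9 and 10, 472 with the Hox score as a covariate and 531 with runs of 3 libraries as a random block. It was 109 with their means as the unit, 1613 with array quality weights and 1628 with DESeq2.

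Both strain comparisons used the same 3 wild-type embryos. They shared 85 genes called higher and 79 called lower, where independent lists would share 8.4 and 7.1 and simulated unchanged groups against these controls shared 0.02 and 0 on average over 100 simulations. In addition, 9 genes were called in opposite directions. The covariance of the fold changes over genes was 0.0896 against a simulated 0.0482 (highest 0.0798), and their correlation was 0.514 against a simulated 0.661. The fold changes had the same sign in 68.2% of genes, against a simulated 73.2%. The simulated groups had no effects, so an overlap of calls near 0 followed from the setting. Strains with separate effects against the same controls were not simulated. With 3 controls the set could not be split, so part of the excess may come from the shared controls.

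NEO-IN versus NEO-OUT compared the strains directly and thereby tested whether their effects differed. p53 targets were lower in NEO-IN, with 6 of 12 called, or 9 adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.207 with an estimated correlation). Ccng1 was at 3560 ± 200 (SD, n = 6) in NEO-IN and 5530 ± 712 (SD, n = 6) in NEO-OUT (log2 fold change -0.62, SE 0.08, limma adjusted p = 7.14e-05), and Perp, Eda2r and Trp53inp1 were 1.32-fold, 1.93-fold and 1.51-fold lower. Each of these 4 genes was lower in all 6 NEO-IN embryos than in any NEO-OUT embryo.

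**Figure D3:**
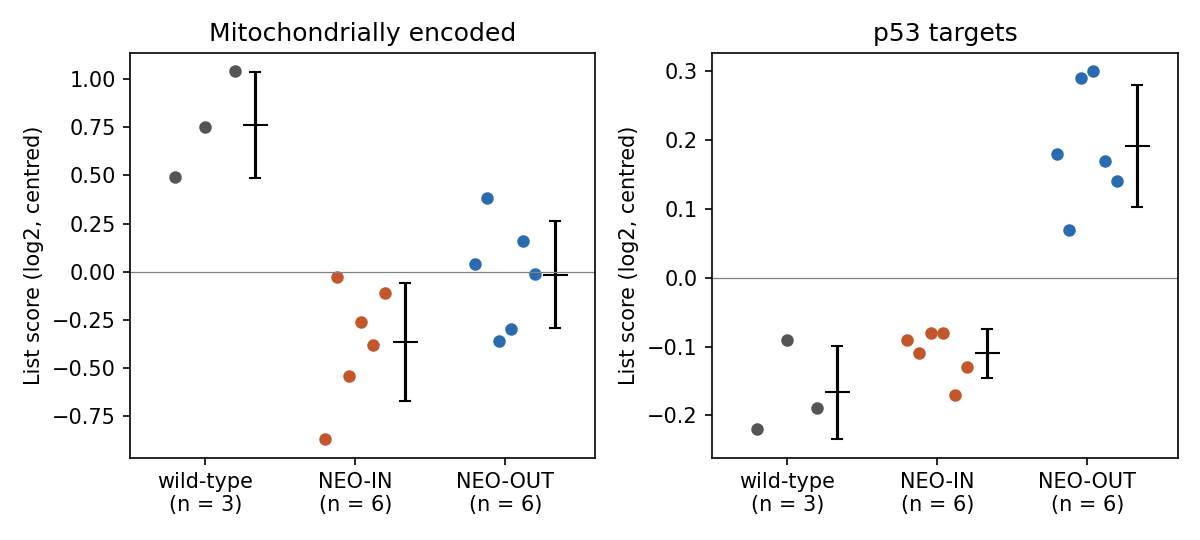
List scores (y axis; mean over the tested members of the log2 value centred on all libraries) for the mitochondrially encoded genes (left) and the p53 targets (right) in each embryo; bars give the mean and SD. The 3 wild-type embryos have the highest mitochondrial scores, from 0.49 to 1.04, and the 6 NEO-OUT embryos the highest p53 scores, from 0.07 to 0.30.

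Node and notochord genes were higher in NEO-IN, with 7 of 8 positive and 3 called, as when adjusted over the list alone: the notochord transcription factor Noto (1.57-fold, limma adjusted p = 0.000844), the secreted signal Shh (1.99-fold, 0.00552) and Pkd1l1, a gene of left-right patterning (1.43-fold, 0.0209). The list had a camera adjusted p of 0.0271 (adjusted p = 0.582 with an estimated correlation) and lost its call without NEO-IN embryo 5 (0.0615). Visceral endoderm genes were lower in NEO-IN in all 13 members, 5 of them called over all genes and adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.582 with an estimated correlation), among them Ttr (1.45-fold, limma adjusted p = 0.000473) and the hepatic nuclear factor Hnf4a (1.17-fold, 0.00265). The Hox list was higher in NEO-IN in 10 of 12 members. Its camera adjusted p was 0.0427 (adjusted p = 0.758 with an estimated correlation), and 0.119 without NEO-OUT embryo 10, 0.0599, 0.0615 and 0.0751 without NEO-IN embryo 3, 5 or 6 and 0.0678 without NEO-OUT embryo 12.

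Cardiac mesoderm, paraxial mesoderm and neuroectoderm (camera adjusted p = 0.314 each) and primitive blood (0.283, with 7 of 16 members positive) were not called between the strains, and called members of the first 3 went both ways. In cardiac mesoderm, Tnnt2 and Myocd, genes of the heart muscle programme, were 1.90-fold and 1.5-fold higher in NEO-IN, while the cardiac regulator Gata4 was 1.22-fold lower (limma adjusted p = 0.0142, 0.0241 and 0.000522). Tnnt2 was at 195.7, 151.1 and 176.2 in NEO-OUT 7 to 9, near the wild-type range of 156.9 to 221.7. It was at 72.45, 106.8 and 91.63 in NEO-OUT 10 to 12, so its difference rests largely on that run. Myocd was at 95.5, 88.4 and 109.7 in NEO-OUT 7 to 9 and at 57.53, 60.73 and 83.99 in NEO-OUT 10 to 12. Myl7, also a heart muscle gene, was lower in NEO-IN (log2 fold change -0.45, limma adjusted p = 0.0142). Myl7 in NEO-OUT 7 and 9 (738.8 and 810.6) lay within the NEO-IN range (509.9 to 860.7), whereas Gata4 did not overlap between the strains. In neuroectoderm, Six3, Hesx1 and Sox11 were 1.56-fold, 1.71-fold and 1.19-fold higher and Lhx2 was 1.63-fold lower (limma adjusted p = 0.0068, 0.0111, 0.00852 and 0.00114). Hesx1 in NEO-OUT 7 and 9 (310.9 and 364.2) lay within the NEO-IN range (308.4 to 541.2). In primitive blood, Alas2, the erythroid enzyme of haem synthesis, and the regulator Gfi1b were 1.95-fold and 1.48-fold lower (0.0105 and 0.00332). Without NEO-IN 6, NEO-OUT 10 or NEO-OUT 11, Myocd had an adjusted p of 0.0565, 0.0541 and 0.0569.

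Further members of the lists were called. In NEO-OUT versus wild-type the log2 fold change was -0.91 for Tbx5, -0.61 for Des and -0.27 for Spry1, and these lost their calls in 10, 7 and 10 of 15 fits without 1 library. In NEO-IN versus NEO-OUT it was 1.22 for Dcn, 0.67 for Stra6, -0.66 for Trf and -0.49 for Bnip3. These kept their calls in all 15 fits, but Dcn, Trf and Bnip3 lost theirs under at least 1 other alternative. The log2 fold change was 0.45 for Cryab, 0.29 for Sp5, 0.27 for Etv4, 0.21 for Egfl7 and 0.18 for Axin2. It was -0.18 for Id2, -0.19 for Ldha and -0.19 for Cyp51. In this order, these genes from Cryab on lost their calls in 12, 7, 8, 5, 6, 12, 5 and 1 of 15 fits.

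The largest differences were near all or nothing. The pseudogene Rps2-ps13 was at 10300 ± 3970 (SD, n = 6) in NEO-IN and 14 ± 4.73 (SD, n = 6) in NEO-OUT, the zinc finger gene Zfp979 was 44.9-fold higher in NEO-IN, and the lipoxygenase gene Alox15 was 39.5-fold lower (limma adjusted p = 4.26e-05, 0.000118 and 0.000101). Counts of the pseudogene are uncertain because its reads can match its parent gene. Wild-type embryos 1, 2 and 3 held both levels, at 8.3, 7548 and 6892 for Rps2-ps13 and at 905, 13.9 and 833 for Zfp979. For Alox15 they were at 919, 1111 and 55.9. The fixed rule also named Ifi204, Nr1h5, Znf41-ps, Abhd12b, B3galt5 and Tpm3-rs7, of which the last 2 lost their calls in 3 and 7 of the 15 fits without 1 library. In total 2180 genes were called between the strains, 1108 higher and 1072 lower in NEO-IN, of which 254 differed by 2-fold or more. Within 30 Mb of Apela 30 of 380 genes were called (7.89%) against 13.4% on other chromosomes. The total was 1218 without the 5 libraries with Y-linked reads 1224 with the Hox score as a covariate, 1432 with runs of 3 libraries as a random block and 250 with their means as the unit.

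**Figure D4:**
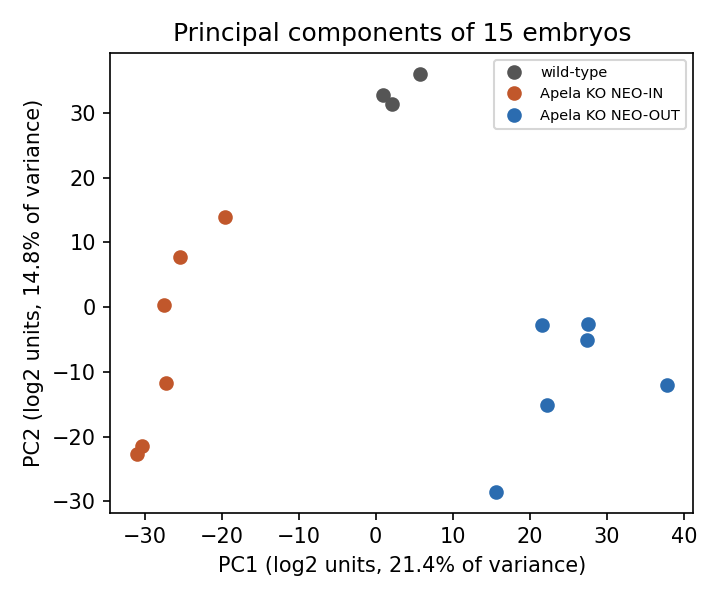
First 2 principal components of log2(normalized count + 1) over the genes tested; each point is 1 embryo, coloured by group. PC1 (21.4% of the variance) runs from -31 to -19.6 in NEO-IN and from 15.6 to 37.8 in NEO-OUT, and PC2 (14.8%) is highest in the 3 wild-type embryos, from 31.3 to 36.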

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

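The tests of the 3 patterns weighed here and the counts over other splits of the libraries were chosen only after the results were seen. The differences between the strains were tested as planned before the data were examined.

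Genes near Apela on chromosome 8 were called more often than others. Within 30 Mb of Apela 14.5% of genes were called in Apela KO versus wild-type, against 2.52% on other chromosomes and 2.29% beyond 50 Mb on chromosome 8. Without the 5 libraries with Y-linked reads the share near Apela was 11.3%, against 1.89% elsewhere, which argues against more males among the knockouts as the whole cause. Among protein-coding genes, 346 of the 380 near Apela, it was 14.7%. This cannot settle reads shared with pseudogenes, since a protein-coding parent gene can share such reads. The share varied with distance, from 20% within 10 Mb to 5.74% from 10 to 20 Mb and 16.7% from 20 to 30 Mb. A candidate explanation is DNA around the Apela allele that was inherited with it and differs from the wild-type chromosomes; between the strains the share near Apela was 7.89% against 13.4% elsewhere. The fixed list of neighbours of Apela was not called in any of the 4 comparisons (camera adjusted p = 0.783, 0.899, 0.629 and 0.682). Of its 7 members tested, 0 were called in Apela KO versus wild-type and 1 was called higher in NEO-OUT versus wild-type. Effects of the allele itself were not otherwise told apart from linked DNA. Fgl1, B3gnt3 and Triml2 may belong to the genes called near Apela.

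Mitochondrially encoded RNA was lower in the knockouts. The score was 0.95 higher in wild-type (log2; exact two-sided permutation p = 0.0022 over 455 splits). It was 0.83 higher without the libraries with Y-linked reads (exact p = 0.0083 over 120 splits), which argues against sex. With each library scaled to its nuclear genes it was 0.959 higher. Normalized totals were nearly equal across libraries and mitochondrial RNA was at most 1.12% of them. This rescaling could therefore hardly move the score, so it cannot decide whether scaling plays a part. The lowest wild-type score lay 0.11 above the highest knockout score, so every wild-type embryo differed from every knockout embryo. Because the knockouts also had knockout mothers, loss of Apela in the embryo, the mothers and their mitochondrial lineage, and a batch of wild-type libraries cannot be told apart. The permutations take embryos as independent, which the runs of 3 libraries among the other observations call into question.

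p53 target RNA was higher in NEO-OUT than in NEO-IN, by 0.3 (log2; exact two-sided permutation p = 0.0022 over 924 splits). Without the libraries with Y-linked reads the difference was 0.31 (exact p = 0.029 over 35 splits), with the Hox score as a covariate 0.27 (p = 0.0022), and the smallest with 1 library left out was 0.28, without NEO-OUT 10. These values argue against sex, stage as measured by Hox genes, and a single library. Litter, handling and the genetic background of the strains stay open as untested explanations. With 2 runs of 3 libraries per strain, splits of whole runs are too few for a share under 0.05, so the permutation p holds only for independent embryos.

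Other splits of the same libraries gave fewer genes than the real groups in each comparison. Of 100 splits, 1, the real one, gave as many as the 465 genes of Apela KO versus wild-type (highest other 17), and of 100 splits 1 gave the 2180 genes between the strains (highest other 22). Of 84 splits, 1 gave the 1043 genes of NEO-OUT versus wild-type (highest other 33) and 1 the 489 of NEO-IN versus wild-type. There the highest other was 175, with NEO-IN 1, 2 and 3 in the place of wild-type, and for NEO-OUT the 33 came with NEO-OUT 10, 11 and 12 in that place. Chance among independent embryos is an unlikely source of these counts, although the share cannot fall below 1 in 84 or 1 in 100. Real differences between groups add to the spread within the other splits, which lowers their counts. A litter, a batch or another difference that goes with the groups stays open.

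The effects of the strains against wild-type differed, by the test of NEO-IN minus NEO-OUT on the log2 scale. The difference was positive for Rps2-ps13 (9.40), Ifi204 (7.79), Zfp979 (5.49), Nr1h5 (4.85), Znf41-ps (3.93), Eif5al3-ps (3.07), Tcf15 (0.68), Foxc1 (0.42), Sox11 (0.25) and Otx2 (0.24). It was negative for Abhd12b (-3.66), Apela (-2.60), Zfp990 (-2.01), Hspa1b (-1.13), Eda2r (-0.95), Ccng1 (-0.62), Ttr (-0.54), Esrrb (-0.44), Perp (-0.40), Phlda3 (-0.40), Insig1 (-0.31), Gata4 (-0.28), Apoa1 (-0.28), Klhl2 (-0.21), Soat2 (-0.18) and Id1 (-0.13). With 1 library left out, Hspa1b lost its call in 12 of 15 fits (adjusted p of 0.0507 to 0.0984; not without NEO-IN 1 or 2 or NEO-OUT 12) and Id1 in 11 (0.0527 to 0.105; not without NEO-IN 3 or NEO-OUT 7, 9 or 12). Soat2 lost its call without NEO-IN 2 (0.0523), NEO-OUT 11 (0.0568) or NEO-OUT 12 (0.0529). Wild-type embryos held both levels of Rps2-ps13, Zfp979 and Nr1h5, so these differences are not plain effects of the knockout strains. Wild-type 1, 2 and 3 were at 8.3, 7548 and 6892, at 905, 13.9 and 833, and at 690, 754 and 16.8. Nr1h5 also split within NEO-IN, at 598 to 1348 in NEO-IN 1 to 4 and at 15.6 and 16.6 in NEO-IN 5 and 6. Eif5al3-ps and Zfp990 split within NEO-IN too. Eif5al3-ps was at 33.03 and 38.66 in NEO-IN 2 and 3, within the NEO-OUT range (15.92 to 41.55), and at 498.2 to 836.8 in the other NEO-IN embryos. Zfp990 was at 423.7, 479.7 and 725.1 in NEO-IN 1, 3 and 4 and at 84.51, 80.02 and 95.73 in NEO-IN 2, 5 and 6. Hspa1b was at 252, 276 and 127 in NEO-IN 1 to 3 and at 73.0, 63.4 and 53.7 in NEO-IN 4 to 6, so its difference between the strains rests on the second run. Among lists the median difference was 0.36 for Hox genes, 0.20 for node and notochord genes, -0.18 for p53 targets and -0.17 for visceral endoderm. These 4 lists were called at the preset correlation, and none with an estimated one (camera adjusted p = 0.758, 0.582, 0.207 and 0.582). With 1 library left out, node and notochord lost the call without NEO-IN 5 (0.0615), and Hox genes without NEO-IN 3, 5 or 6 (0.0599, 0.0615 and 0.0751) or NEO-OUT 10 or 12 (0.119 and 0.0678).

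Single libraries stood far from the other 5 of their strain in 30 of 348 values tested, where chance gives about 1 in 20. In NEO-IN these were the endothelial score (0.45) and Cer1 (1780) in embryo 6, Snai1 (1120) and Vegfa (2520) in embryo 1, Hbb-bs (0) and Sox17 (1740) in embryo 2, and Perp (1940) in embryo 3. NEO-IN embryo 4 stood apart for Apela (25.9, others 5.83 to 9.91), Ifi204 (0, others 691 to 1410), Glns-ps1 (21.2) and Meox1 (639), and embryo 5 for Rsad1 (303) and Eda2r (129). NEO-OUT embryo 10 had low Wnt target (-0.48) and FGF target (-0.34) scores, Hoxb1 (1740), Dusp6 (3200) and Glns-ps1 (37.3). NEO-OUT embryo 9 had a high score of macrophage genes (4.88, others -0.86 to 0.25) and high Lyz2 (3690, others 9.36 to 41.1). The macrophage list was written after the data were seen and holds Lyz2, so these 2 values record the same observation. In this embryo Zmat3 (3010) was high and Fcgrt (123), Foxc2 (721), Pou3f1 (1250), Msx2 (2660), Eomes (2040) and Lhx2 (208) were low. Its Ifi204 value (3.92, others 0) was near the floor. Hspa1b was low in NEO-OUT embryo 12 (147) and Ripply2 in NEO-OUT embryo 8 (27.8).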

How the results depend on the processing

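The alternatives without the 5 libraries with Y-linked reads, without NEO-OUT 9 and 10, with the Hox score, with protein-coding autosomal genes, with halved reads, without chromosome 8 and with runs of 3 consecutive libraries were chosen only after the data were seen. Apela kept its direction and its call in all 4 comparisons under each alternative that tested it. The 150 gene results include Apln and Aplnr in all 4 comparisons, which were not called and had no call to lose. Of the 150, 82 lost their call with means of 3 consecutive libraries as the unit and 42 with these runs as a random block. With the trophoblast score as a covariate 58 lost their call and 1, the uncalled Apln in NEO-OUT versus wild-type, reversed. The call was lost by 49 with the Hox score, 44 without the libraries with Y-linked reads, 31 without NEO-OUT 9 and 10 and 29 with no filter. DESeq2 lost 7, equal totals 6 and TMM scaling 0.

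Counts of called genes that moved by more than 1.5 times are given here, and the cause was not tested. For Apela KO versus wild-type, NEO-IN versus wild-type and NEO-OUT versus wild-type they were 865, 800 and 1613 with array quality weights, 900, 928 and 1628 with DESeq2, and 83, 108 and 336 with the trophoblast score as a covariate. With runs of 3 consecutive libraries as a random block they were 188, 237 and 531, and 1432 for NEO-IN versus NEO-OUT; with means of each run as the unit, which leaves 1 wild-type unit assumed to vary like the others, they were 73, 71, 109 and 250. Apela KO versus wild-type had 300 with the Y-linked level as a covariate and 175 with the 12 knockouts as 1 group. NEO-OUT versus wild-type had 583 without NEO-OUT 9 and 10 and 472 with the Hox score, and NEO-IN versus NEO-OUT had 1218 without the libraries with Y-linked reads and 1224 with the Hox score.

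With 1 library left out, Apela KO versus wild-type ranged from 153 (without wild-type 1; 160 and 200 without 2 and 3) to 477, NEO-IN versus wild-type from 206 (without wild-type 2; 239 and 223 without 1 and 3) to 598, and NEO-OUT versus wild-type from 383 (without wild-type 1; 421 and 500 without 2 and 3) to 1232. NEO-IN versus NEO-OUT ranged from 1673 to 2245. With the replicate block, NEO-IN versus wild-type had 487 genes, 222 of them shared with the result without it, though the numbers did not pair the libraries.

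The direction of the list test reversed for the trophoblast list in NEO-IN versus wild-type (median 0.03) and for the Hox list in NEO-IN versus NEO-OUT (median 0), each with its own score as a covariate, which follows from adjusting a list for itself. With the trophoblast score the primitive streak list in NEO-IN versus wild-type had a median of 0.02 (adjusted p = 0.994). Apln in NEO-OUT versus wild-type, not called, was 0.02 with the trophoblast score, and Aplnr in NEO-IN versus NEO-OUT, not called, ranged from -0.05 to 0.01 with 1 library left out. Of 21 list results, 5 lost their call with the Y-linked level, 4 with quality weights and 3 without the libraries with Y-linked reads, and 4 of 15 did with protein-coding autosomal genes, among them trophoblast in Apela KO versus wild-type (0.0716). List calls with means of 3 libraries rest on 1 wild-type unit and on the preset correlation, so they cannot measure stability. Depth limits genes near the floor, such as Fgl1 in wild-type.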

Other observations

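The tests in this part, of runs of consecutive libraries, clusters along chromosomes and blood and Hox scores, were chosen only after the results were seen.

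The split by consecutive numbers parted the libraries farthest. Over 15702 autosomal genes, 1 of 100 joint splits of the strains into 3 and 3 libraries, the one by consecutive numbers, gave this distance (mean squared log2 distance 0.213, highest other 0.204). Single pairs did not always follow the runs. By chi-square per degree of freedom, NEO-OUT 9 was farther from NEO-OUT 7 and 8 (41.2 and 32.6) than from NEO-OUT 10 (26.1). NEO-IN 3 was farther from NEO-IN 1 (24.2) than from NEO-IN 5 (20.4). A litter or batch shared by each run of 3 is a candidate explanation. In NEO-IN the runs also differ in Y-linked reads, and in NEO-OUT each run holds 1 library with them. With means of 3 libraries as the unit, 73 genes were called in Apela KO versus wild-type, 71 and 109 in NEO-IN and NEO-OUT versus wild-type, and 250 between the strains.

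Genes called between NEO-IN and NEO-OUT lay in clusters. Over 123 windows of 20 Mb with at least 20 genes, the variance of the called share was 1.42 times its mean over 10000 shuffles (one-sided permutation p = 0.009), and 3 windows had more calls than the rest by a test adjusted over windows, among them chromosome 4 from 140000001 to 160000000 with 52 of 216 genes called (24.1%, adjusted p = 0.00262). A candidate explanation is inherited segments that differ between the strains, which had a mixed background. Neighbouring genes may also be regulated together, which the shuffles ignore.

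Primitive blood and Hox scores went together within each strain but failed the test. Pearson's r was 0.67 in NEO-IN (p = 0.165) and 0.79 in NEO-OUT (p = 0.0861), with an adjusted p of 0.165 for both. Small differences of stage within a strain could produce this, and 6 embryos cannot decide.

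Some genes were present in part of a group and near absent in the rest. Of 13462 genes with a mean of at least 50, with Y-linked genes and Xist left out, 39 had a gap of 16-fold or more between neighbouring libraries of a group. Rps2-ps13 was at 8.3 in wild-type embryo 1 and at 7548 and 6892 in the others, and Ifi204 was at 0 in NEO-IN embryo 4.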
